A study of Homo sapiens with 14 samples.

How the data were processed

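RNA was sequenced from areas of human breast tumor sections that had been cut out by laser capture microdissection. Per the labels, the libraries fall into 4 groups: TLS-rich HEV (n = 4), TLS-rich non-HEV (n = 4), TLS-free non-HEV (n = 4) and TLS-rich non-EC tissue (n = 2). TLS are tertiary lymphoid structures, HEV are high endothelial venules and EC are endothelial cells. The 14 libraries were assigned to their group by title, and 0 table columns were left unassigned. The titles of the 2 non-EC libraries do not give the tumor type.

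The table deposited by the authors holds a normalized signal for 60658 genes, 1 column per library. In each column 100% of the values are whole multiples of 1 step, within a tolerance of 0.01 of a read, so each value is a gene read count divided by 1 factor per library. The whole reads were recovered by that step. The 2 gene lists deposited by the authors hold log2 fold changes of the MECA79 stain over the CD31 stain. Per the file headers these lists also hold each gene's p-value and adjusted p. STAR 2.5.3a, HTSeq 0.6.1, DESeq2 1.6.3 and the genome build hg19 are named in the submitters' processing notes without their roles. The strand on which reads were counted is not given in the sources used here. Gene positions in the text come from GENCODE release 29 on GRCh38, a later build than the one counted on, and were matched by gene identifier for 73 of 73 genes looked up.

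The libraries held between 4661815 and 13112310 reads in genes, and between 17279 and 23846 genes had a read. In the deposited unit, 1 read in 1 library was worth between 0.577 and 1.67. Where a group had 0 reads of a gene, the fold is given as "at least", against a floor of 3 reads over the whole group. Where a group had 1 to 3 reads, the ratio of the group means is given with its 95% counting interval in place of the fitted fold change. These floors and intervals cover counting error only, since the reads carry no molecular identifiers.

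Genes with a value of at least 10 in at least 4 of the 14 libraries were tested, which left 17219 of the 40319 genes that had a read. Values were transformed as log2(value + 1). One limma model with a mean per group was fitted to all 14 libraries, with trended empirical Bayes and 10 residual degrees of freedom. The 5 contrasts taken from it were HEV against non-HEV in TLS-rich tumors, non-HEV in TLS-rich against TLS-free tumors, TLS-rich HEV against TLS-free non-HEV, HEV against the mean of both non-HEV groups, and TLS-rich endothelium (mean of HEV and non-HEV) against non-EC tissue. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The p-values measure only the spread between these samples.

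A set of 45 gene lists, of cell types, vessel types, pathways and RNA classes, was tested with limma's camera. Camera asks whether a list's genes shift more than the other genes tested, here with the correlation between genes estimated from the residuals. List p-values were adjusted over the 45 lists of a comparison. A list level per library is the mean of its members' centred log2 values, compared between groups by a two-sided exact permutation test. For 4 against 4 libraries the smallest p that this test can give is 0.0286. The contrasts, lists, tests, filter and all alternatives not named below as later ones were fixed before the data were examined.

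Named genes follow a rule fixed at the same time. In each comparison these are the 10 largest positive and 10 largest negative fold changes among genes past the threshold. Every library of one group had to lie on the same side of the other group's mean, and the higher group's mean had to be at least 50. Where fewer than 5 genes qualified in a direction, the 5 with the lowest p are given as values. Each list described adds up to 4 members past the threshold, or its 2 members with the lowest p, and each deposited list adds its 5 largest folds per direction. Left out were clones without a symbol, immunoglobulin and T cell receptor segments (treated as groups), sex-linked marker genes, and genes that germline deletions remove in some people.

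Alternatives were a pseudocount of 0.5 or 4, no filter, a filter on a mean of at least 50, TMM rescaling, quantile normalization, a fit to the compared groups only, array weights, robust empirical Bayes, and leaving out each library in turn. The replicate number was also used as a block, the recovered reads were tested with edgeR's quasi-likelihood test and with DESeq2, and the lists with camera at a preset correlation of 0.01 and with fry. Added after seeing the data were limma voom on the recovered reads and the mitochondrial RNA share as a covariate. Leaving out together the 2 non-HEV libraries with the highest such share was also added then. These were TLS-rich non-HEV replicate 3 (34.6%) and TLS-free non-HEV replicate 2 (43.9%), while TLS-rich HEV replicate 3 (34.4%) was kept.

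The pipeline was tested on simulated data with 50 genes seeded at each log2 change. Only genes with a mean value of at least 50 were seeded, so the shares called do not cover lower genes. For HEV against non-HEV in TLS-rich tumors it called 6% of genes seeded at 2, 38% at 3, 48% at 4 and 64% at 6, and 4 of 16202 unchanged genes. For non-HEV in TLS-rich against TLS-free tumors these shares were 4%, 20%, 40% and 72%, with 5 of 16179 unchanged genes called. For TLS-rich HEV against TLS-free non-HEV they were 6%, 36%, 48% and 76%, with 4 of 16243. For HEV against all non-HEV they were 14%, 34%, 54% and 82%, with 7 of 16156. For endothelium against non-EC tissue they were 6%, 18%, 32% and 58%, with 14 of 16183. The seeded list was called in each comparison, but the run was set to stop otherwise, so that call is no test. Camera called 0 of 44 lists without a seeded change. The simulated genes varied independently of each other, so these lists do not show how camera acts on lists of correlated genes.

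The work used R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.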

Results

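High endothelial venules (HEV) are the vessels through which lymphocytes leave the blood in lymphoid tissue, and they also form in tumors that hold tertiary lymphoid structures (TLS), which are organized lymphocyte aggregates. Areas of human breast tumor sections were taken by laser capture microdissection, in which stained structures are cut from the section under a microscope, and their RNA was sequenced. Per the labels, HEV were picked by the MECA79 antibody, which binds the sugar ligands on HEV, and other (non-HEV) vessels by CD31, the product of PECAM1. A higher level of PECAM1 or of the genes that make the MECA79 ligand in captures picked by these stains is therefore no finding. The list of MECA79 ligand synthesis and carriers did not, however, separate the 2 TLS-rich vessel groups. Its level was 0.46 ± 0.40 in TLS-rich HEV, 0.49 ± 0.60 in TLS-rich non-HEV and 0.10 ± 0.28 in TLS-free non-HEV. Tested with camera, it passed in no comparison between vessel groups. The groups were TLS-rich HEV (n = 4), TLS-rich non-HEV (n = 4), TLS-free non-HEV (n = 4) and endothelium-free (non-EC) tissue of TLS-rich tumors (n = 2). The labels do not tie libraries to tumors. Values below are normalized read counts, mean ± SD over these libraries, and fold changes are fitted log2 differences with their standard error (SE).

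Reads in genes per library, in replicate order, were 4661815, 9772309, 10611480 and 7807148 in TLS-rich HEV, and 5677728, 8890578, 10985575 and 13112310 in TLS-rich non-HEV. They were 6261290, 6352289, 9808055 and 8056853 in TLS-free non-HEV, and 5161873 and 5257342 in non-EC tissue. Mitochondrial RNA took 25.4% ± 6.96 of the reads in TLS-rich HEV, 22.7% ± 8.82 in TLS-rich non-HEV, 26.9% ± 11.6 in TLS-free non-HEV and 24.9% ± 4.36 in non-EC tissue. Pearson correlations between replicates, across genes and so not over independent units, lay between 0.599 and 0.747. On the first principal component, which held 15.4% of the variance, the 2 non-EC libraries lay at −243 and −189 and the 12 vessel libraries between −73.0 and 94.9.

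Captured endothelium of TLS-rich tumors carried far more RNA of vessel wall genes such as MCAM and CDH5 than non-EC tissue, and less RNA of B cell genes. MCAM, an adhesion molecule of vessel walls (ENSG00000076706, chromosome 11, 119308529 to 119321521), averaged 843 ± 720 over the 8 vessel libraries against 1 read in non-EC tissue, a ratio of 1245 (95% counting interval 223 to 49179.8, adjusted p 2.19e-07). The tight junction gene ESAM had a ratio of 663 (119 to 26174), and the actin-binding gene SHROOM4 a ratio of 935 (168 to 36919.5). With 0 reads in non-EC tissue, NR5A2, a nuclear receptor gene, was at least 219-fold higher and ADGRG1, an adhesion receptor gene, at least 195-fold higher. The endothelial cadherin CDH5 rose by 6.22 (SE 0.74, adjusted p 1.26e-05), from 9.44 ± 1.86 in non-EC tissue to 804 ± 632 in non-HEV and 1049 ± 566 in HEV. Of the B cell genes, the complement receptor CR2 (ENSG00000117322, chromosome 1, 207454230 to 207489895) fell by 8.14 (SE 1.76, adjusted p 0.00804). The CD20 gene MS4A1 fell by 4.78 (SE 1.18), from 10804 ± 4511 in non-EC tissue, and BANK1, a B cell adaptor, by 5.56 (SE 1.40). In all, 450 of 17219 genes passed, 420 higher and 30 lower, with the median of all genes at 0.29. Quantile normalization moved that median by −0.33 and gave 259 higher and 20 lower. edgeR called 90 genes (61 higher, 29 lower) and DESeq2 1512 (1304 and 208). Voom, chosen after seeing the data, turned the balance, with 2 higher and 92 lower, 32 of these 94 shared with the 450. Without non-EC replicate 1 or 2, where the lone non-EC library is assumed to vary like the other groups, 274 and 394 genes passed, and 10 of the 20 named genes in each case.

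Of 23 pan-endothelial genes, 15 rose, 0 fell and 8 did not pass (19 rose adjusted over the list alone), among them VWF, the platelet-binding factor of endothelium, by 5.99, and the VEGF receptor FLT1 by 5.23. The list itself had an adjusted p of 0.0812. Pericyte and matrix genes moved with them: 7 of 17 pericyte genes rose (10 adjusted over the list alone), such as NOTCH3 by 4.39, and 11 of 25 basement membrane genes (18 alone), such as NID1 by 7.05, while both lists had an adjusted p of 0.146. The B cell list fell, with 4 of 18 members lower, 0 higher and 14 not passing (14 lower adjusted over the list alone), a median of −4.52 and an adjusted p of 0.0450. The leukocyte common list fell with 1 of 16 members (8 alone), PTPRC, which encodes CD45, by 2.37 (list adjusted p 0.0450). The germinal center list fell (0 of 14 members, 2 alone, adjusted p 0.0467), with the B cell regulator RGS13 at −6.02 (adjusted p 0.0712). The list of MECA79 ligand genes also passed (3 of 12 members, 6 alone, adjusted p 0.0454), which is no finding, since the captures were selected by that stain and CD31. For each of the other 3 lists that passed, all 8 vessel libraries lay on one side of both non-EC libraries (exact permutation p 0.0222, 0.0476 adjusted, two-sided). All of these list calls were lost without any 1 of TLS-rich non-HEV replicates 1 and 2, HEV replicates 1 and 2 and non-EC replicates 1 and 2, which left 0 lists called by camera (8 to 13 at an unadjusted p under 0.05).

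**Figure D1:**
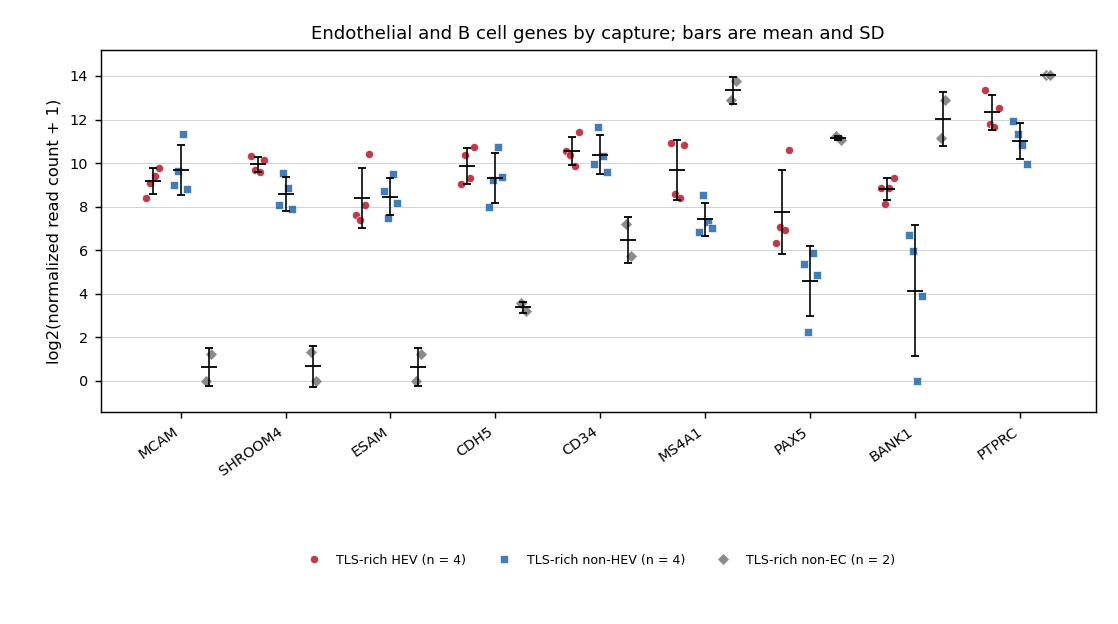
Log2(normalized read count + 1) of endothelial and leukocyte genes per library in TLS-rich HEV (n = 4), TLS-rich non-HEV (n = 4) and non-EC tissue (n = 2), with mean and SD as bars. MCAM, SHROOM4 and ESAM have at most 1 read in all of the non-EC tissue, where MS4A1 averages 10804.

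Within TLS-rich tumors, HEV captures held less RNA of the plasma cell list than non-HEV captures and more of the T cell and dendritic cell lists. Single stromal genes such as DCN and POSTN were lower too, while the fibroblast list as a whole did not pass. JCHAIN, which joins secreted antibody (ENSG00000132465, chromosome 4, 70655541 to 70681817), fell by 5.63 (SE 1.02, adjusted p 0.0132), from 4326 ± 2613 to 104 ± 123. DERL3, which clears misfolded proteins in secretory cells (ENSG00000099958, chromosome 22, 23834503 to 23839128), fell by 5.95 (SE 1.18, adjusted p 0.0293), from 767 ± 569 to 12.9 ± 11.6. ELL2, an elongation factor of antibody-secreting cells, fell by 2.29 (SE 0.47, adjusted p 0.0379), from 1985 ± 160 to 415 ± 111. The matrix gene DCN (ENSG00000011465, chromosome 12, 91140484 to 91183123) fell by 3.04 (SE 0.55, adjusted p 0.0132), from 4972 ± 4350 to 573 ± 368. Further stromal genes that fell were POSTN by 2.97, the Wnt modulator SFRP2 by 4.07, MXRA5 by 2.39 and the scavenger receptor LRP1 by 3.14. The imprinted noncoding RNA MEG3 fell by 3.80, and UNC5B, a guidance receptor of arterial endothelium (ENSG00000107731, chromosome 10, 71212570 to 71302864), by 5.28 (SE 1.02, adjusted p 0.0241), from 648 ± 641 to 11.9 ± 6.09. The lincRNA FENDRR (ENSG00000268388, chromosome 16, 86474529 to 86509099) rose, from 3 reads over the 4 non-HEV libraries to 182 ± 127 in HEV, a ratio of 241 (95% counting interval 82.4 to 1167, adjusted p 0.0303). GABRA2, a GABA receptor subunit gene, rose from 1 read to 147 ± 87.6, a ratio of 517 (92.8 to 20432, adjusted p 0.0496). The only other gene that rose, the unnamed lincRNA RP11-622O11.2, lies outside the naming rule and was chosen after its values were seen. The T cell factor TCF7 measured 849 ± 463 in HEV and 95.9 ± 61.3 in non-HEV (adjusted p 0.0533), the alarmin IL33 2429 ± 692 and 337 ± 134 (adjusted p 0.0568), and the homing chemokine CCL19 1743 ± 700 and 190 ± 79.9 (adjusted p 0.0625), none of which passed. In all, 23 genes passed, 3 higher and 20 lower. Quantile normalization gave 9 higher and 25 lower, DESeq2 72 and 139, voom 3 and 3, and edgeR 0 (1217 at an unadjusted p under 0.05, against 1093 in limma). The count fell to 5 without TLS-rich non-HEV replicate 1, 14 without replicate 2 and 6 without replicate 3, and to 5, 10 and 8 without HEV replicates 2, 3 and 4. Of the 12 named genes that passed, 0 still did without non-HEV replicate 1 or 3 or HEV replicate 2 or 4, 4 without non-HEV replicate 2, 8 without replicate 4, and 7 and 3 without HEV replicates 1 and 3.

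**Figure D2:**
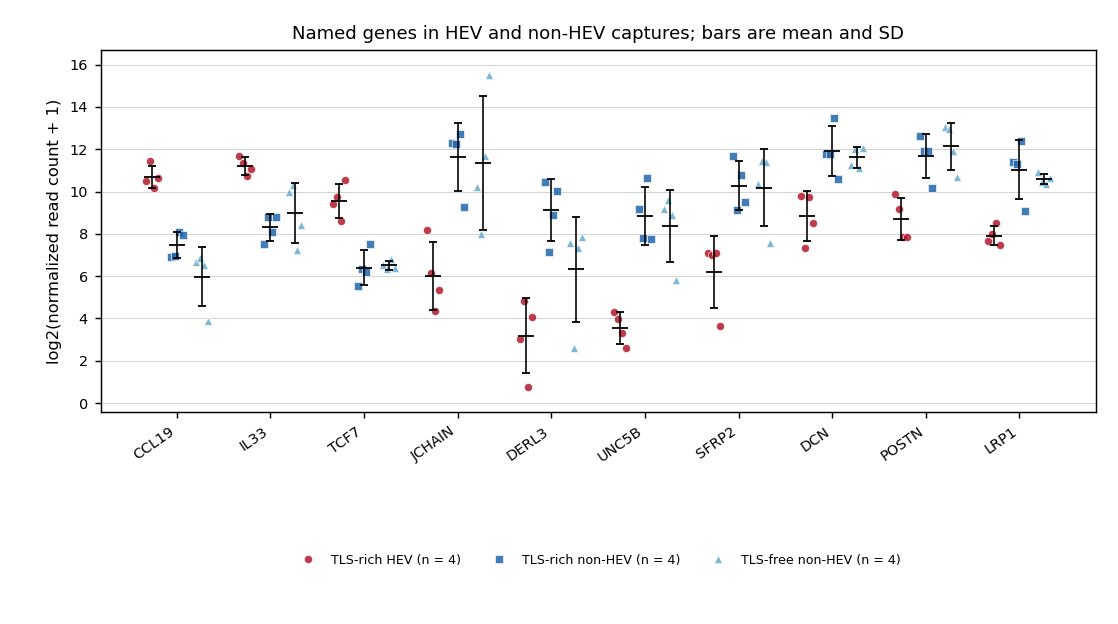
Log2(normalized read count + 1) of 10 genes in TLS-rich HEV, TLS-rich non-HEV and TLS-free non-HEV libraries (n = 4 each), points per library with mean and SD as bars. CCL19 averages 1743 in HEV against 190 and 79.9 in the other vessels, and DCN 573 against 4972 and 3282.

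Of 19 plasma cell genes, 8 fell in HEV against TLS-rich non-HEV, 0 rose and 11 did not pass (16 fell adjusted over the list alone), with a median of −4.29 and an adjusted p of 0.0272 for the list. Immunoglobulin constant genes led it: IGKC averaged 6122 ± 5508 in HEV and 115629 ± 61210 in non-HEV, and IGHG1 1815 ± 1758 and 47091 ± 31622. Of 77 immunoglobulin genes tested, 9 fell, 0 rose and 68 did not pass, and 76 had a negative fold change. The list of protein folding and unfolded protein response genes fell (adjusted p 0.0235, median −0.89) with 0 of 22 members passing (2 fell adjusted over the list alone). Its chaperone HSP90B1 measured 2398 ± 240 in HEV and 6720 ± 1710 in non-HEV (adjusted p 0.0880), and SEL1L, of the degradation pathway, had a fold change of −1.74 (adjusted p 0.195). The T cell list rose (adjusted p 0.0360, median 2.02) with 0 of 22 members passing (8 adjusted over the list alone), and the adaptor TRAT1 measured 231 ± 114 in HEV and 14.2 ± 24.4 in non-HEV (adjusted p 0.0962). The dendritic cell list rose (adjusted p 0.0360, median 2.05) with 0 of 12 members passing (0 alone), and the homing receptor CCR7 measured 675 ± 465 and 68.4 ± 70.5 (adjusted p 0.567). In each of these 4 lists all 4 HEV libraries lay beyond all 4 non-HEV libraries (exact permutation p 0.0286, 0.143 adjusted, two-sided). Of 22 fibroblast genes 3 fell (12 alone, list adjusted p 0.161), and of 17 arterial genes 1 fell (4 alone, list adjusted p 0.223). Of 23 venous and HEV endothelial genes 0 passed (11 higher alone), with 21 positive and an adjusted p of 0.126. Without TLS-rich non-HEV replicate 4 or HEV replicate 4 camera called 0 lists (9 and 7 at an unadjusted p under 0.05), with the plasma cell and protein folding lists at 0.0576 and 0.0521. Without non-HEV replicate 2 or HEV replicate 1 it called 2, with the T cell list at 0.0869 and 0.112 and the dendritic cell list at 0.0863 and 0.118. With the replicate number as a block camera called 0 lists (8 at an unadjusted p under 0.05), so all 4 list calls ended. It also called 0 lists (10 unadjusted) without the 2 non-HEV libraries of highest mitochondrial share, with all 4 lists at 0.0731. That alternative was chosen after seeing the data. It kept HEV replicate 3, whose share of 34.4% was close to the 34.6% of the dropped TLS-rich non-HEV replicate 3. The level differences stayed about as large with these 12 libraries, at −3.45 (SE 0.74) against −3.79 (SE 0.75) with all for plasma cells, −0.97 (SE 0.21) against −0.96 (SE 0.19) for protein folding, 2.36 (SE 0.45) against 2.04 (SE 0.45) for T cells and 1.99 (SE 0.54) against 1.79 (SE 0.48) for dendritic cells, each SE from the fit to all groups. Over 15 alternatives the adjusted p ran from 5.30e-21 to 0.0731 for the plasma cell list, 3.77e-05 to 0.0731 for protein folding, 2.41e-10 to 0.121 for T cells and 0.000531 to 0.164 for dendritic cells.

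**Figure D3:**
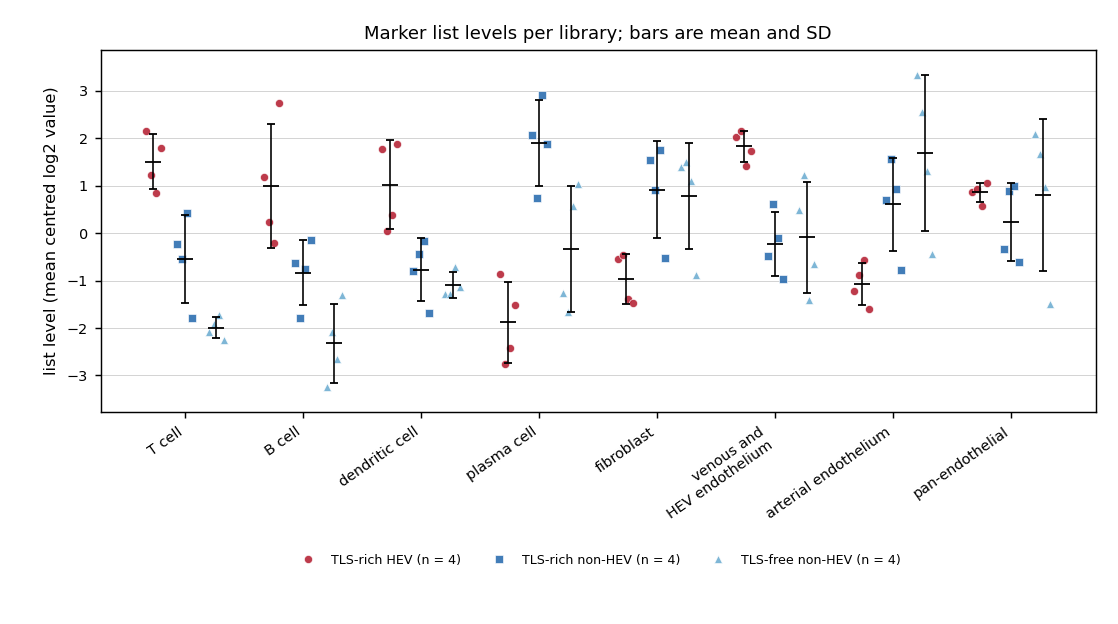
Level of 8 marker lists per library, as the mean of the members' centred log2 values, in TLS-rich HEV, TLS-rich non-HEV and TLS-free non-HEV (n = 4 each), with mean and SD as bars. The plasma cell level averages −1.88 in HEV and 1.90 in TLS-rich non-HEV, and the T cell level 1.50 and −0.54.

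Non-HEV captures of TLS-rich tumors held more RNA of an interferon-induced chemokine and of a cytokine receptor than those of TLS-free tumors. They also held more of leukocyte and checkpoint lists. Chance is not excluded here, since 2 of 35 splits of these libraries, the real one included, gave as many genes and 2 as many lists. CXCL9, which attracts activated T cells (ENSG00000138755, chromosome 4, 76001275 to 76007488), rose by 3.03 (SE 0.52, adjusted p 0.0263), from 655 ± 725 to 3772 ± 1461. IL21R, the receptor of interleukin 21 on lymphocytes (ENSG00000103522, chromosome 16, 27402162 to 27452042), rose by 6.77 (SE 1.21, adjusted p 0.0313), from 1.26 ± 1.61 to 260 ± 202. Of the 77 immunoglobulin genes, IGHG1 rose by 4.90 (SE 0.75, adjusted p 0.00752), 0 fell and 76 did not pass, while 75 of the 77 had a positive fold change (median 2.99). Values that did not pass were the interleukin 10 receptor IL10RA at 1300 ± 1146 against 114 ± 76.6 (adjusted p 0.0702), and the interferon-induced gene GBP5 at 3.57 (adjusted p 0.114). In the other direction 0 genes passed in limma. The 5 with the lowest p there, at an adjusted p of 0.269 to 0.294, were the small nucleolar RNA SNORA28 at 1.61 ± 1.86 against 151 ± 124, SHISA6 with 1 read against 74.8 ± 33.4 (ratio 343, 95% counting interval 61.5 to 13538), the chemokine CXCL14 at 641 ± 426 against 3310 ± 2673, the hemoglobin gene HBA1 with 0 reads against 70.5 ± 107 (at least 113-fold) and the stress-induced gene SESN3 at 803 ± 275 against 2798 ± 1419. Thus 3 genes passed, 3 higher and 0 lower, against 1244 at an unadjusted p under 0.05. edgeR called 0 (1399 unadjusted) and DESeq2 140 higher and 69 lower. Without TLS-rich non-HEV replicates 1, 2 and 3 there were 0, 1 and 0 genes (1204 and 1091 unadjusted beside each 0), and without TLS-free replicates 2, 3 and 4 there were 5, 12 and 11. Neither CXCL9 nor IL21R passed without TLS-rich non-HEV replicate 1, 2 or 3, and 1 of them without TLS-free replicate 2.

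The leukocyte common list was higher in TLS-rich than in TLS-free non-HEV captures (adjusted p 0.0252, median 1.53) with 0 of 16 members passing (9 adjusted over the list alone), and the integrin ITGAL measured 766 ± 308 against 183 ± 77.9 (adjusted p 0.294). The immune checkpoint list was higher too (adjusted p 0.0252, median 2.77) with 0 of 15 members passing (3 alone). Its inhibitory receptor CTLA4 measured 176 ± 180 against 12.7 ± 23.8 (adjusted p 0.294), and the tryptophan enzyme IDO1 117 ± 119 against 0 reads (adjusted p 0.290). In both lists all 4 TLS-rich libraries lay above all 4 TLS-free ones (exact permutation p 0.0286, 0.214 adjusted, two-sided). Of 19 interferon gamma response genes 1 rose (14 alone, list adjusted p 0.0629), and of 9 chemokines of lymphoid structures 1 rose (5 alone, list adjusted p 0.101). Of 19 plasma cell genes 1 rose (10 alone), 18 were positive and the list did not pass (adjusted p 0.148), with levels of 1.90 ± 0.90 in TLS-rich and −0.33 ± 1.33 in TLS-free non-HEV. Both list calls were lost without TLS-rich non-HEV replicate 1 (0.0801 each) or 3 (0.0537) and TLS-free replicate 1 (0.0816) or 4 (0.0750), which left 0 lists in camera (6 to 12 at an unadjusted p under 0.05). The leukocyte common call was also lost without TLS-free replicate 3 (0.0555, 1 list left), and 4 lists were called without TLS-rich non-HEV replicate 4. Over 14 alternatives the adjusted p ran from 1.30e-09 to 0.107 for the leukocyte common list and 7.56e-07 to 0.107 for the checkpoint list.

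**Figure D4:**
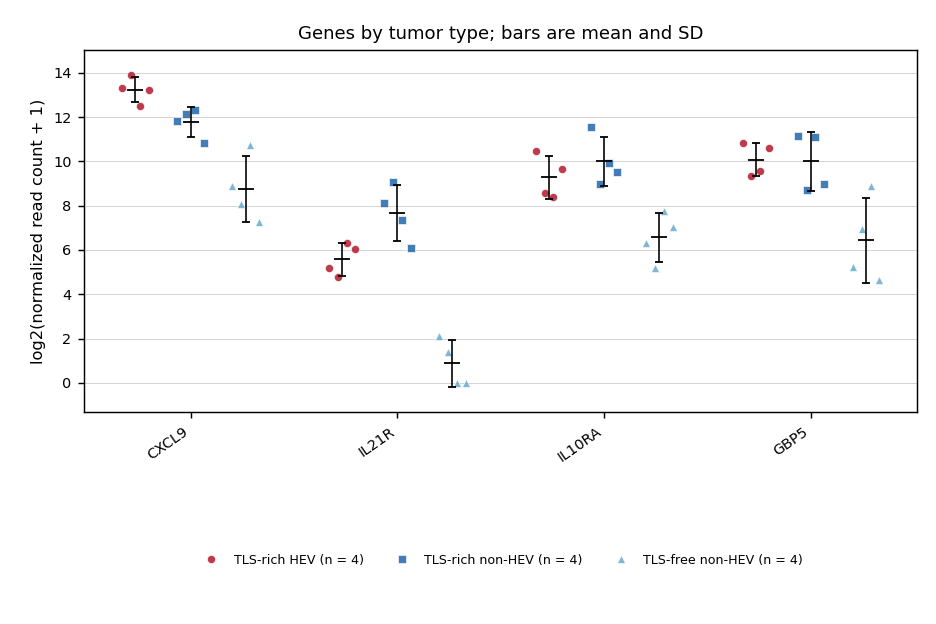
Log2(normalized read count + 1) of 4 immune genes per library in TLS-rich HEV, TLS-rich non-HEV and TLS-free non-HEV (n = 4 each), with mean and SD as bars. CXCL9 averages 10194 in HEV, 3772 in TLS-rich non-HEV and 655 in TLS-free non-HEV, and IL21R 260 and 1.26 in the latter pair of groups.

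Set against vessels of TLS-free tumors, where vessel and tumor type both differ, HEV captures held more RNA of lymphocyte, chemokine and antigen presentation lists. Single arterial and stromal genes such as SEMA3G and SFRP2 were lower, while the arterial and fibroblast lists did not pass. CXCL9 rose by 4.48 (SE 0.52, adjusted p 4.22e-05), from 655 ± 725 to 10194 ± 3904, and the related chemokine CXCL11 by 6.92 (SE 1.29), from 16.9 ± 32.8 to 484 ± 202. CCL19 (ENSG00000172724, chromosome 9, 34689567 to 34691277) rose by 4.71 (SE 0.71, adjusted p 0.00340), and its receptor gene CCR7 by 6.73 (SE 1.31, adjusted p 0.0188), from 6.82 ± 8.24 to 675 ± 465. MS4A1 (ENSG00000156738, chromosome 11, 60455752 to 60470760) rose by 6.27 (SE 1.06, adjusted p 0.00777), from 57.9 ± 104 to 1130 ± 888. The Fc receptor-like gene FCRL3 rose by 6.15 (SE 1.03), from 2.39 ± 1.96 to 210 ± 63.5, and the olfactory receptor gene OR2I1P by 7.14 (SE 1.26), from 26.7 ± 53.3 to 498 ± 222. The T cell genes TESPA1, SCML4 and CRTAM and the selectin ligand SELPLG also rose. FENDRR, with 0 reads in TLS-free non-HEV, was at least 224-fold higher. SEMA3G, an arterial semaphorin (ENSG00000010319, chromosome 3, 52433053 to 52445085), fell from 138 ± 126 to 0 reads in HEV, at least 210-fold lower. JCHAIN fell by 5.34, UNC5B by 4.81, SFRP2 by 3.98, the BMP receptor BMPR1B by 6.63 and the potassium channel gene KCNN3 by 5.66. In all, 63 genes passed, 44 higher and 19 lower, against 4 by edgeR, 367 by DESeq2 and 8 by voom (8 higher, 0 lower, with 1470 at an unadjusted p under 0.05). The count fell to 21, 16, 28 and 7 without HEV replicates 1 to 4 and to 31 without TLS-free replicate 1. Of the 20 named genes, 8, 7, 7 and 2 still passed without HEV replicates 1 to 4, and 10, 11, 11 and 11 without TLS-free replicates 1 to 4, with OR2I1P alone passing in every case.

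In all, 11 lists passed in HEV against TLS-free non-HEV. The T cell list rose with 3 of 22 members (18 adjusted over the list alone, median 3.40, adjusted p 0.00517): THEMIS by 5.37, IL7R by 3.40 and CD6 by 5.60. The leukocyte common list rose with 6 of 16 members (13 alone, adjusted p 0.00517), such as PTPRC by 2.44 and the integrin ITGAL by 2.77. MHC class II genes, which present peptides to T cells, rose with 3 of 12 members (9 alone, adjusted p 0.0158): CD74 by 1.64, HLA-DMA by 3.78 and HLA-DRB1 by 2.77. Chemokines of lymphoid structures rose with 3 of 9 members (7 alone, adjusted p 0.0178), interferon gamma response genes with 4 of 19 (13 alone, adjusted p 0.0178), dendritic cell genes with 2 of 12, CCR7 and LAMP3 (2 alone, adjusted p 0.0178), and B cell genes with 2 of 18, MS4A1 and PAX5 (8 alone, adjusted p 0.0200). Checkpoint genes (0 of 15, 5 alone, adjusted p 0.0158), cytotoxic genes (0 of 12, 5 alone, adjusted p 0.0178) and lymphotoxin pathway genes (0 of 19, 2 alone, adjusted p 0.0178) rose as lists. The heat shock and immediate early list fell (0 of 16, 2 alone, adjusted p 0.0245), with the early response factor EGR1 at 933 ± 143 against 4801 ± 4046 (adjusted p 0.0757). In each of the 11 lists all 4 HEV libraries lay beyond all 4 TLS-free ones (exact permutation p 0.0286, 0.0857 adjusted, two-sided). Of 17 arterial genes 2 fell (7 alone, list adjusted p 0.0510), and of 22 fibroblast genes 4 fell (12 alone, list adjusted p 0.104). Of the 11 calls, 8 held without any 1 library. The B cell list was lost without TLS-free replicate 1 (0.0573) or 3 (0.0586), the cytotoxic list without TLS-free replicate 3 (0.0586), and the heat shock list without TLS-free replicate 2 (0.0514) or HEV replicate 2 (0.0697). Over 14 alternatives the adjusted p of these 3 lists ran from 1.36e-11 to 0.0586, 1.73e-06 to 0.0638 and 5.73e-05 to 0.0697.

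Against both non-HEV groups together, HEV captures held more RNA of the chemokine, venous and T cell lists and less of the plasma cell list. All HEV libraries are TLS-rich and 1 of the 2 non-HEV groups is TLS-free, so vessel and tumor type are partly mixed here. Against TLS-rich non-HEV alone, only 2 lists rose past the threshold, those of T cells and dendritic cells. Against TLS-free non-HEV alone, the plasma cell list did not pass. Single matrix and arterial genes such as SFRP2 and UNC5B were lower, while the fibroblast and arterial lists did not pass. CCL19 rose by 3.96 (SE 0.62, adjusted p 0.00282), TCF7 (ENSG00000081059) by 3.11 (SE 0.59, adjusted p 0.0159), IL33 (ENSG00000137033) by 2.55 (SE 0.55, adjusted p 0.0338) and the chemokine-scavenging venous receptor ACKR1 by 2.88 (SE 0.65, adjusted p 0.0473). FENDRR, with 3 reads over the 8 non-HEV libraries, had a ratio of 481 (95% counting interval 165 to 2335, adjusted p 0.00408). JCHAIN fell by 5.48 (SE 0.88, adjusted p 0.00374), UNC5B fell by 5.05 (SE 0.89, adjusted p 0.00623) and SFRP2 by 4.02 (SE 0.71, adjusted p 0.00645). SEMA3G was at least 269-fold lower, and the collagen gene COL11A1, with 2 reads in HEV, had a ratio of 710 (197 to 5862) of non-HEV over HEV. In all, 51 genes passed, 20 higher and 31 lower. Quantile normalization gave 43 higher and 42 lower, edgeR 17 and 9, and DESeq2 140 and 199. Array weights gave 92 higher and 78 lower and voom 51 and 1, so the excess of lower genes does not hold across settings. The count fell to 24 without TLS-rich non-HEV replicate 1 and to 22, 15, 23 and 14 without HEV replicates 1 to 4, and rose to 86 without TLS-free replicate 4. CCL19, FENDRR, JCHAIN and UNC5B passed without any 1 library. Of the 20 named genes, 6, 6, 7 and 6 passed without HEV replicates 1 to 4, 8, 14, 14 and 14 without TLS-rich non-HEV replicates 1 to 4, and 16, 18, 14 and 18 without TLS-free replicates 1 to 4. The authors' deposited lists name 53 genes higher in MECA79 than in CD31 captures and 41 lower. Of these 48 and 40 were tested, all with the deposited direction, and 9 and 18 passed. Which libraries entered these lists is not stated, and as part of the same data set they are not taken as independent evidence. The largest deposited folds include MMP9, a matrix protease gene, at 3.76 here (adjusted p 0.444), and PM20D1. PM20D1 was not tested, because too few libraries reached the filter value. It measured 53.2 ± 91.8 in HEV and 0 reads in the 8 non-HEV libraries.

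The lists that rose in this comparison were those of T cells (2 of 22 members, 16 adjusted over the list alone, adjusted p 0.0124), leukocytes (2 of 16, 8 alone, adjusted p 0.0195), dendritic cells (1 of 12, 2 alone, adjusted p 0.0198), MHC class II (0 of 12, 8 alone, adjusted p 0.0293), cytotoxic cells (0 of 12, 2 alone, adjusted p 0.0293), the lymphotoxin pathway (0 of 19, 2 alone, adjusted p 0.0302), B cells (1 of 18, 8 alone, adjusted p 0.0309), chemokines of lymphoid structures (2 of 9, 5 alone, adjusted p 0.0318) and venous and HEV endothelium (3 of 23, 11 alone, adjusted p 0.0499). The authors' list holds CD3D and CD3E of the T cell list and CCL19 and IL33 of the venous list. Plasma cell genes fell (5 of 19, 13 alone, adjusted p 0.0293), as did the protein folding (0 of 22, 3 alone, adjusted p 0.0293) and heat shock lists (0 of 16, 2 alone, adjusted p 0.0434). Neither the plasma cell nor the protein folding list passed against TLS-free non-HEV alone. The plasma cell level was −1.88 ± 0.86 in HEV, 1.90 ± 0.90 in TLS-rich non-HEV and −0.33 ± 1.33 in TLS-free non-HEV. Protein folding levels were −0.35 ± 0.27, 0.61 ± 0.17 and −0.15 ± 0.33 in the same order. All 4 HEV libraries lay above all 8 non-HEV libraries for the T cell and dendritic cell levels (exact permutation p 0.00202, 0.0455 adjusted, two-sided) and for the venous level (0.00404, 0.0490 adjusted). Of 22 fibroblast genes 5 fell (12 alone, list adjusted p 0.0540), and of 17 arterial genes 2 fell (8 alone, list adjusted p 0.0540). All list calls of the 5 comparisons, made at the estimated correlation, also passed with fry. They passed too with camera at the preset correlation, which allows for less correlation and so is no independent check. The T cell and leukocyte calls held without any 1 library. Without HEV replicate 4 these were the 2 calls left, and without HEV replicate 2 there were 7, with the plasma cell and protein folding lists at 0.0533 and 0.0529. The B cell list was also lost without HEV replicate 1 (0.0539) or TLS-free replicate 1 (0.0598), the lymphotoxin list without TLS-rich non-HEV replicate 4 (0.0578), the chemokine list without that library (0.0511), HEV replicate 1 (0.0539) or 2 (0.0533) or TLS-free replicate 1 (0.0598), and the venous and heat shock lists without 9 of the 12 libraries each, at up to 0.0909 and 0.0923 without HEV replicate 2. Over 18 alternatives the adjusted p ran from 3.22e-14 to 0.0657 for plasma cells, 0.00207 to 0.0766 for protein folding, 1.36e-10 to 0.0668 for B cells, 0.00124 to 0.0766 for the lymphotoxin pathway, 2.62e-06 to 0.0766 for chemokines, 1.24e-10 to 0.0909 for venous endothelium and 0.000352 to 0.0923 for heat shock genes.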

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

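The tests on the T cell level minus the plasma cell level, on the T cell and B cell shares of the non-EC level, on the checkpoint list at an equal mitochondrial share and without both libraries of high share were chosen only after the result was seen. The values singled out first are libraries far from the other 3 of their group on the log2 scale, measured by the gap to the nearest library over the group's whole range. Of 333 such groups checked, 34 stood out, where chance gives about 1 in 20, or 16.65, for normally distributed values. Of the 34, 17 were in TLS-free non-HEV, 11 in TLS-rich non-HEV and 6 in TLS-rich HEV. The genes checked were named from the same data, so 34 against 16.65 is no test of an excess over chance.

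In 15 groups the gap was 1, because 3 libraries had 0 reads and 1 library had some. Such a group stands out however few its reads, so the chance rate given above does not hold for it. In TLS-rich non-HEV these were GABRA2 in replicate 1, LINC00310 and TPBGL in replicate 2, SHISA6 and ANKRD53 in replicate 3 and TCL1A in replicate 4. In TLS-free non-HEV they were OR2I1P, TESPA1, CRTAM and TPBGL in replicate 2 and SELPLG and APCDD1L in replicate 3. In TLS-rich HEV they were COL11A1 in replicate 1, MTHFS in replicate 2 and LINC00310 in replicate 3.

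Lower than the others of their group were CCL19 in TLS-free non-HEV replicate 4 (gap 0.894, log2 value 3.88 against 6.52 to 6.84), DERL3 in TLS-free replicate 2 (0.901) and JCHAIN in TLS-rich non-HEV replicate 4 (0.865, log2 value 9.26 against 12.25 to 12.72). IGKC was low in TLS-rich non-HEV replicate 2 (0.905), SFRP2 in HEV replicate 4 (0.962), STEAP1 in HEV replicate 1 (0.914), ELL2 in TLS-free replicate 2 (0.831), CSRP2 in TLS-free replicate 2 (0.922), TTC6 in TLS-free replicate 1 (0.831) and HTRA3 in TLS-free replicate 4 (0.858). Higher than the others were SHISA6 (0.863) and MTHFS (0.840) in TLS-free replicate 3, PAX5 in TLS-free replicate 4 (0.894), BMPR1B in HEV replicate 4 (0.836), MMP9 in TLS-rich non-HEV replicate 1 (0.833) and CHST2 in TLS-rich non-HEV replicate 3 (0.830). Among list levels, the immune checkpoint list was high in TLS-rich non-HEV replicate 3 (0.872), the heat shock and immediate early list in TLS-free replicate 2 (0.870) and the list of MECA79 ligand synthesis and carriers in TLS-free replicate 1 (0.893).

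T cell and B cell markers were higher in HEV than in TLS-free non-HEV captures, with T cell levels of 1.50 ± 0.58 and −1.99 ± 0.22 (n = 4 each). The T cell level differed by 3.49 (SE 0.31) and the plasma cell level by −1.55 (SE 0.79), a gap of 5.04 (SE 0.72). A lower endothelial share that raises all other cell types alike needs about no gap, so these values argue against it. Both lists were picked after their change was seen, so the gap is no independent test and does not exclude that explanation. RNA of tissue with the make-up of the non-EC captures cannot be told apart, because the T cell share of the non-EC level over the B cell share ran from 1.09 to 18.4 over the 8 pairs of an HEV and a non-EC library (median 4.55), with HEV replicate 4 at 1.09 and 3.98 and the other 3 HEV libraries at 4.21 to 18.4. Lymphocytes in or on the HEV wall may also bring this RNA, and so may the difference in tumor type, neither of which was tested. In 1 of the 35 splits of these 8 libraries, the real one, were there as many genes (63, highest other 3). In 1 of 35 were there as many lists (11, highest other 1). Chance is thus unlikely but not excluded as the source of both counts, since 1 of 35 is the lowest share this test can give.

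Plasma cell and protein folding lists were lower in HEV than in TLS-rich non-HEV captures, with plasma cell levels of −1.88 ± 0.86 and 1.90 ± 0.90 (n = 4 each). The T cell level differed by 2.04 (SE 0.55) and the plasma cell level by −3.79 (SE 0.62). The gap was 5.83 (SE 0.53, each SE from these libraries alone). A higher endothelial share in HEV that lowers all other cell types alike needs about no gap, so these values argue against it. The 2 lists were picked after they were seen to move apart, so the gap is no independent test and does not exclude that explanation. Less plasma cell RNA may carry the lower protein folding list: its difference was −0.96 (SE 0.19) as measured and −0.54 (SE 0.33) at an equal plasma cell level, within 2 SE of 0 in a fit to 14 libraries, so the pair cannot be told apart. A lower secretory load of the HEV endothelium itself was not tested. In 1 of the 35 splits of these libraries were there as many genes (23, highest other 1), and in 1 of 35 as many lists (4, highest other 0). Chance is thus unlikely but not excluded, since 1 of 35 is the lowest share this test can give. The splits also take the libraries as unpaired, which stays open.

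Leukocyte common and immune checkpoint lists were higher in TLS-rich than in TLS-free non-HEV captures. At an equal mitochondrial RNA share the leukocyte difference was 1.99 (SE 0.30) against 2.01 (SE 0.28) as measured. The checkpoint difference was 2.39 (SE 0.44) against 2.45 (SE 0.42). A linear effect of that share thus did not carry either difference. The shares of the groups were close, at 22.7% ± 8.82 in TLS-rich and 26.9% ± 11.6 in TLS-free non-HEV, so the adjustment had little to move. Without the 2 non-HEV libraries of highest share the leukocyte and checkpoint differences were 1.86 (SE 0.32) and 2.28 (SE 0.52), about as large. With the 12 libraries left, however, camera called 0 lists (7 unadjusted), with both lists at 0.107. That was the highest of their 14 alternatives (lowest 1.30e-09 for the leukocyte and 7.56e-07 for the checkpoint list). More leukocyte RNA may carry the checkpoint list, whose difference was 2.45 (SE 0.42) as measured and 1.27 (SE 0.99) at an equal leukocyte level, and both cannot be told apart because the leukocyte levels of the groups do not overlap, with the tumor type itself also open and untested. Of the 35 splits, 2 gave as many genes (3, highest other 3) and 2 as many lists (2, highest other 4), so chance is not excluded for either count.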

How the results depend on the processing

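The tests with voom, with the mitochondrial share as a covariate and without the 2 non-HEV libraries of highest share came after the results were seen. Under every setting run, all genes called in a comparison that were still tested had the direction reported, and 0 results that had passed reversed. A change of sign in a result that had not passed was not counted as a reversal. The called genes had log2 changes of 1.63 or more and were refitted on the same data, so their directions could hardly turn. The counts of genes moved, and except where stated the cause was not tested. The 5 comparisons are given in the order HEV against TLS-rich non-HEV (23 genes), TLS-rich against TLS-free non-HEV (3), HEV against TLS-free non-HEV (63), HEV against all non-HEV (51) and endothelium against non-EC tissue (450). With no filter on low values, 40319 genes were tested and 0, 0, 3 and 0 genes passed in the first 4, where limma had 1847, 1915, 2243 and 2025 at an unadjusted p under 0.05 and more genes shared the correction. A pseudocount of 4 gave 7 genes in the second comparison. Quantile normalization gave 85 genes in the fourth and 279 in the fifth. A fit to the compared groups alone gave 64 genes in the first and 33 in the third. Array weights gave 75, 121, 170 and 281 in all but the second, and robust empirical Bayes gave 0 (1235 unadjusted) in the second. edgeR called 0, 0, 4, 26 and 90 genes, with 1217 and 1399 at an unadjusted p under 0.05 in the first 2, and DESeq2 called 211, 209, 367, 339 and 1512. Of the genes called by limma, DESeq2 also called 23, 3, 59, 49 and 431. Voom called 6 (3 higher, 3 lower), 0 (1242 unadjusted), 8 (8 and 0), 52 (51 and 1) and 94 (2 and 92), so that its balance of calls was opposite to that reported in the fourth (20 and 31) and the fifth (420 and 30). Leaving out the 2 non-HEV libraries of highest mitochondrial share, with HEV replicate 3 (34.4%) kept, gave 11 in the first. Leaving out 1 library gave 5 to 27 genes in the first comparison, 0 to 12 in the second, 7 to 62 in the third, 14 to 86 in the fourth and 274 to 473 in the fifth, with fewer samples in each.

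Camera called 4, 2, 11, 12 and 4 lists at the estimated correlation and 21, 17, 28, 28 and 25 at the preset correlation of 0.01, which by construction allows for less correlation within lists. Fry, which does not compare a list with other genes, called 6, 17, 19 and 26 lists in the last 4. Quantile normalization left 2 lists in the first comparison, 3 in the fourth and 0 (13 unadjusted) in the fifth. Without the 2 non-HEV libraries of highest mitochondrial share camera called 0 lists in the first, the second and the fifth (10, 7 and 10 unadjusted). Leaving out 1 library gave 0 to 6, 0 to 4, 9 to 15, 2 to 14 and 0 to 4 lists.

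With the replicate number as a block, camera called 0 lists (8 unadjusted) in HEV against TLS-rich non-HEV, and 20 genes passed, 19 of them shared with the 23. In HEV against all non-HEV the block gave 36 genes, 32 shared with the 51. Residual correlations of libraries with the same number lay between −0.00761 and 0.0665 over the 4 pairs. The same number was the best match for 3 of 4 HEV and 2 of 4 non-HEV libraries, so whether the numbers pair tumors stays open.

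For single named genes, 9914 values under the alternatives stayed on their side of the threshold, 1105 no longer passed and 237 newly passed. For single lists these counts were 3184, 127 and 154, and for list levels 221, 1 and 3. The first count of each kind also holds any result that had not passed and changed its sign. Of the 88 deposited genes tested, 88 had the authors' direction as reported and with a pseudocount of 4, TMM rescaling and the block. The median SE, which comes from the spread between libraries, was 1.30 on the log2 scale, and the smallest fold change that passed between HEV and TLS-rich non-HEV was 2.29. How much of that spread is due to sequencing depth was not tested. Depth does limit folds against groups with 0 reads, which are lower bounds.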

Other observations

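The shares of the non-EC level were chosen only after the result was seen, unlike the other tests in this part. The pan-endothelial list passed in no comparison between vessel types. The pan-endothelial level was 0.86 ± 0.20 in HEV, 0.24 ± 0.82 in TLS-rich non-HEV and 0.81 ± 1.61 in TLS-free non-HEV (n = 4 each), with an adjusted p of 0.580 for HEV against TLS-rich non-HEV. By replicate it was 2.09, 1.68, 0.98 and −1.50 in TLS-free and −0.34, 0.89, 0.99 and −0.60 in TLS-rich non-HEV. TLS-free replicate 4 thus had the lowest level of the vessel libraries. Leaving it out gave 11 genes between the non-HEV groups and 86 in HEV against all non-HEV, against 3 and 51. The Notch ligand DLL4 measured 12.4 ± 10.1 in HEV, 195 ± 162 in TLS-rich non-HEV and 381 ± 381 in TLS-free non-HEV, and the receptor NOTCH4 95.5 ± 31.3, 813 ± 408 and 832 ± 827, and neither passed in any comparison of HEV. The BMP signal transducer SMAD1 measured 1393 ± 398, 356 ± 261 and 922 ± 228 (adjusted p 0.191 for HEV against TLS-rich non-HEV). The terminal complement gene C7 was higher in HEV than in TLS-free non-HEV by 3.14 (SE 0.68, adjusted p 0.0335), at 1279 ± 315 against 175 ± 125. The platelet and leukocyte selectin gene SELP measured 1871 ± 337 in HEV, 300 ± 172 in TLS-rich non-HEV and 3.47 ± 2.74 in non-EC tissue.

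Type I interferon genes had positive fold changes for 25 of 25 members in non-HEV vessels of TLS-rich against TLS-free tumors (median 2.14, 0 passing over all genes and 5 adjusted over the list alone, list adjusted p 0.246). Proliferation genes were positive for 18 of 21 (3 alone, list adjusted p 0.148), with the topoisomerase TOP2A at 609 ± 355 against 95.6 ± 71.2. Of 7 T cell receptor genes tested, 0 passed in limma in any comparison, and 7 were positive in HEV against all non-HEV, with a median of 1.85. Macrophage genes were negative for 18 of 19 in HEV against TLS-rich non-HEV, but 0 passed in limma, over all genes or adjusted over the list alone (lowest unadjusted p 0.00416, of the scavenger receptor MSR1), the list did not pass (adjusted p 0.241), and the levels overlapped (−0.39 ± 0.74 and 1.12 ± 1.09).

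Set against each of the 2 non-EC libraries, the median T cell member reached 34.3% to 141% of its non-EC level in HEV libraries, 4.75% to 42.8% in TLS-rich non-HEV and 2.54% to 9.09% in TLS-free non-HEV. The median B cell member reached 4.13% to 18.7% in HEV replicates 1 to 3, 27.1% and 53.5% in HEV replicate 4, 0.935% to 6.80% in TLS-rich non-HEV and 0.0625% to 1.69% in TLS-free non-HEV. For plasma cell members these ranges were 3.64% to 77.6%, 51.3% to 674% and 13.3% to 198%, and each vessel library's share was higher against non-EC replicate 2 than against replicate 1.

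In HEV against all non-HEV, 1 of 100 splits drawn, the real one, gave as many genes (51, highest other 12). The same 1 of 100 gave as many lists (12, highest other 0). Chance is thus unlikely but not excluded for both counts, since 1 of 100 is the lowest share these draws can give.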
